A study of Homo sapiens with 12 samples.

How the data were processed

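Gene expression was measured in primary human epidermal keratinocytes, the cell type given in the labels, at passage 8. The 12 samples form 6 groups of 2: untreated cells (CTL), and cells given TNF alone, or TNF with cannabidiol (CBD), bakuchiol (BAK), ethyl (linoleate/oleate) (ELN), or BAK and ELN mixed 1:1 by weight. Treatment lasted 24 hours. Doses are not given in the labels. RNA was purified with a Qiagen kit, converted to biotin-labelled cDNA with the GeneChip WT kit and read on Affymetrix arrays.

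The deposited values are log2 signals of probe sets made by RMA, per the submitters' processing notes, that is, background correction, quantile normalization between arrays and a median polish per probe set. The version of RMA and the software that ran it are not given in the sources used here. Each array has 1 column of values, and all 12 columns were used. The table holds 27189 rows, of which 21448 are transcript clusters and 5741 are controls or other rows. A single gene symbol was paired with 17709 transcript clusters, all matched by gene number to the reference table, 0 had several symbols, and 3739 have no gene name here. For the 17 genes with more than 1 probe set, the probe set with the highest mean over the 12 arrays stood for the gene. XIST and Y-linked genes were left out of every test, which left 17663 named genes. Arrays have no read depth. Their number, 2 per group, limits the precision, and the level of 612 negative-control probe sets served as background: their 95th percentile lay between 4.82 and 4.99 log2 across the arrays.

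Genes were tested when their mean over the 12 arrays was at or above the 25th percentile of named genes (5.08 log2), which kept 13247 genes. A linear model with 1 mean per group was fitted to all 12 arrays in limma 3.58.1 under R 4.3.3 (lmFit, contrasts, eBayes with an intensity trend), so that the 6 groups shared 1 estimate of the spread with 6 residual and 6.30 prior degrees of freedom. There were 10 comparisons: TNF against CTL; each of the 4 compound groups against TNF; the BAK by ELN interaction, which is the combination minus TNF+BAK minus TNF+ELN plus TNF; and the combination against TNF+BAK, TNF+ELN and TNF+CBD, and TNF+BAK against TNF+CBD. A gene is said to have risen, fallen or changed when its two-sided p, adjusted by Benjamini and Hochberg over the genes tested, was under 0.05. Values after ± are standard errors of the log2 difference from limma unless they are called SD, and each group had n = 2. With 2 arrays against 2, the smallest p of an exact permutation test is 0.333, so the gene tests rest on the shared estimate of the spread.

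The comparisons, the rule for naming genes and 29 gene lists were fixed before the data were examined. The lists are NF-kB targets and regulators, chemokines, cytokines and growth factors of inflammation, interferon response, antimicrobial and S100 genes, antigen presentation, matrix proteases and wound genes, keratinocyte differentiation, basal keratinocyte genes, cell cycle, cholesterol synthesis (SREBP2), fatty acid synthesis and LXR targets, PPAR targets and fatty acid oxidation, NRF2 targets, integrated stress and unfolded protein response, heat shock genes, metallothioneins, AHR targets, retinoid response, endocannabinoid system, eicosanoid synthesis, EGFR ligands and immediate early genes, p53 targets, hypoxia and glycolysis, and markers of melanocytes, fibroblasts, immune cells, endothelial cells and Merkel cells. Each list with at least 5 measured genes was tested in each comparison with camera in limma, two-sided, with a preset correlation between genes of 0.01, and the 290 p-values were adjusted together. Camera with a correlation estimated from the arrays and fry were run beside it. With an estimated correlation camera called 0 of the 290 tests, also for lists in which most members changed by limma. The calls made with the preset correlation therefore depend on that setting, and none of them held with a correlation taken from these arrays. Fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. Counts of members past the threshold are given over all genes tested and adjusted over the list alone.

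Genes were named by rule. In the comparisons against TNF or CTL and the interaction, these are the up to 8 largest rises and the up to 8 largest falls among the genes that changed, and in the other 4 comparisons the up to 4 largest each way. Where fewer than 3 genes passed in a direction, the 3 with the smallest p were taken and are said not to pass. Added to these are the up to 4 members with the smallest p of each list that camera called, and a set of inflammatory, endocannabinoid and lipid genes in every comparison. Other genes named are members of the lists that passed, or markers given for their level, and were chosen after their values were seen.

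For the genes that TNF changed, each compound's effect was set beside 100 simulations with no compound effect, the same shared TNF arrays and each group's own spread, since comparisons that share arrays are related without any effect. In them genes vary independently, so they hold no movement shared by genes on an array. The same simulations served the covariances between compounds. The gene tests were also tested on simulated data in which each gene had the same spread in all groups (20 simulations, 200 changed genes). The groups measured here differed in spread, from 0.738 times the pooled spread in TNF+BAK to 1.68 times in TNF+ELN. The shares that follow hold for equal spread only. A change of 1 log2 was recovered for 80.5% of genes in TNF+CBD against TNF and 35.8% in the interaction, a change of 0.5 log2 for 11.3% and 1.4%, and 5.05% of calls were false in both. Permutation tests used scipy 1.17.1, with the two-sided p as 2 times the smaller one-sided p, and tables pandas 2.3.3, under Python 3.11.15.

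The alternatives tried were no filter, a filter at the median, no intensity trend, robust eBayes, a fit of the compared groups alone, arrays centred on their medians, cyclic loess, array quality weights, the replicate number as a block, the mean of probe sets, and each array left out in turn. A pair of settings was added after the data were seen: TNF+ELN replicate 1 left out of every fit, and the TNF+ELN group left out. The exact permutation test of the combination against the single compounds was also chosen after the data were seen.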

Results

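The arrays gave log2 signals for 17663 named genes in 6 groups of 2 arrays. Array medians lay between 6.35 and 6.4 log2, and 12691 named genes (71.9%) lay above the negative controls on all 12 arrays. At the median standard error, the 95% interval of a log2 difference between 2 groups reached 0.356 to either side, and that of the interaction 0.503. The labels do not say whether the 2 arrays of a group came from separate cultures. The p-values of single genes therefore measure only the spread between these samples, which may be technical. Camera's p-values set the genes of a list against the other genes. They rest on the preset correlation of 0.01, so very small ones do not show that a difference would recur in new samples. Of the 612 negative-control probe sets, 0 changed in any of the 10 comparisons by limma (20 to 44 at an unadjusted p under 0.05).

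Most fibroblast markers gave high signals, and several genes of epidermal epithelium lay near the negative controls. DCN and LUM, proteoglycans of connective tissue, had means over the 12 arrays of 12.25 and 11.13 log2, COL1A2, a chain of type I collagen, 11.61, VIM, an intermediate filament of mesenchymal cells, 11.43, FAP 11.20 and PDGFRA 10.70. Of the 13 named fibroblast markers 12 lay above the negative controls on all arrays, the exception being MFAP5 at 4.76, and the median marker lay at percentile 97.9 of named genes. KRT14, a keratin of basal keratinocytes, had a mean of 4.85, KRT10 and KRT1, keratins of differentiating cells, 4.97 and 4.73, and IVL, an envelope protein, 4.48. The integrins ITGB4 and ITGA6, which anchor basal keratinocytes, had 4.44 and 3.81, the desmosomal cadherin DSG3 3.83, and GRHL2 and ESRP1, regulators of epithelial identity, 3.84 and 3.31. Other keratins were higher: KRT5 had 6.84, KRT16 8.30 and KRT7 9.31. Of 46 abundant epithelial genes 26 lay above the negative controls on all arrays, where 71.9% of all named genes did, and 8 on none. The median of 47 differentiation genes lay at percentile 23.4, and 17 of them lay above the negative controls on no array. The 12 basal keratinocyte genes had their median at percentile 90.8, and the highest of these, ITGB1, CD44 and CAV1, are also expressed by fibroblasts. Markers of melanocytes, immune cells, endothelial cells and Merkel cells had medians at percentiles 28.3, 18.7, 44.2 and 25.3. Levels of different probe sets depend on their affinity, so these are ranks and not amounts of RNA.

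**Figure D1:**
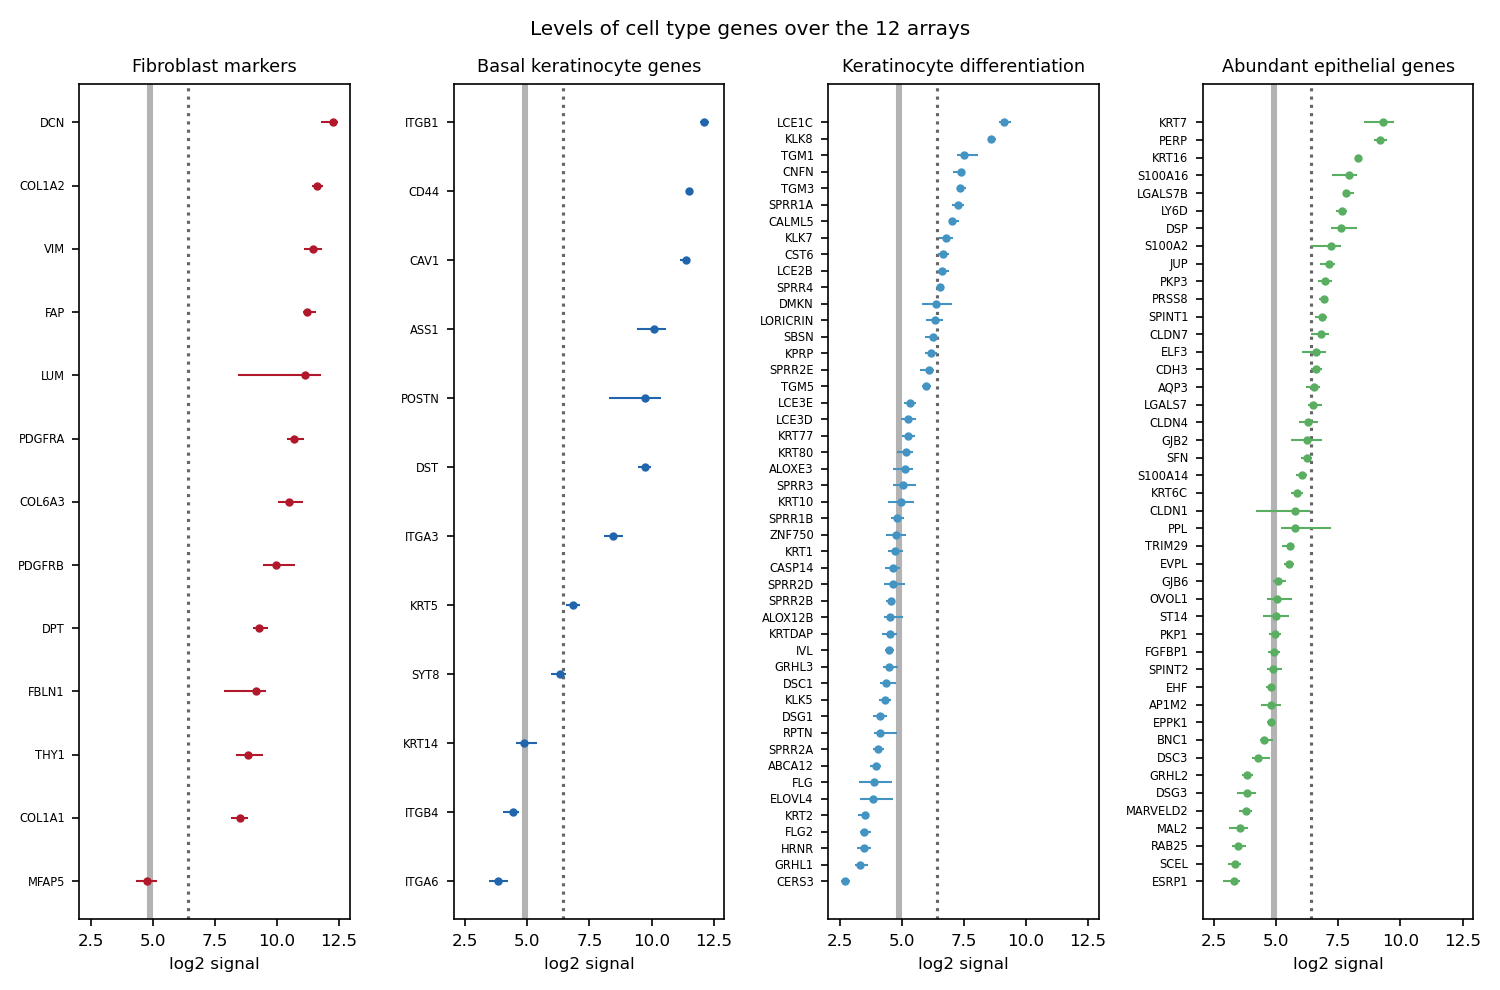
Mean log2 signal over the 12 arrays (points) with the lowest and highest array (lines) for fibroblast markers, basal keratinocyte genes, keratinocyte differentiation genes and abundant epithelial genes; the grey band is the 95th percentile of the negative controls across arrays (4.82 to 4.99) and the dotted line the median of named genes (6.42). Of the 13 fibroblast markers 12 lie above the band on all arrays, while KRT14, ITGB4 and ITGA6 lie in it or below it.

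One array stood apart from its group. TNF+ELN replicate 1 correlated across genes with its replicate at r = 0.977, against 0.987 to 0.994 in the other 5 groups, where genes are not independent replicates. On it 369 genes lay at least 1 log2 below the mean of the 8 TNF-treated arrays of other groups, and 53 at least 1 log2 above. The largest deviations, chosen after their values were seen, were ATP5F1A, a subunit of mitochondrial ATP synthase, at 4.52 on this array and 7.57 on the other TNF+ELN array, and RGS2, a regulator of G protein signalling, at 7.94 and 6.55. The median of the positive controls was 9.36 on this array and on CTL replicate 2, and 9.48 to 9.53 on the other 10. The within-group spread of TNF+ELN was 1.68 times the pooled spread, against 0.738 to 1.15 in the other groups.

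What TNF itself did to these cells was asked first. TNF against CTL changed 1217 genes, 645 of which rose and 572 fell, and 466 changed by at least 2-fold. The largest rise was that of IL6, a cytokine of the acute phase, which was 32.8-fold higher (log2 difference 5.04 ± 0.20, adjusted p = 2.5e-08). TFPI2, a protease inhibitor, was 32.2-fold higher, CFB, complement factor B, 25.9-fold, and TNFAIP6, a hyaluronan-binding protein of inflammation, 24.1-fold (4.59 ± 0.10, adjusted p = 7.8e-11). The largest falls were those of SEMA3A, a guidance cue for axons and vessels, 5.37-fold lower (-2.42 ± 0.28, adjusted p = 0.00014), and AQP1, a water channel, 4.79-fold lower. GDF10, a growth factor of the TGF-beta family, was 4.32-fold lower, PDE7B, a cAMP phosphodiesterase, 4.27-fold, and RCAN2, a regulator of calcineurin, 3.73-fold. PTCH1, the hedgehog receptor, ROBO2, a receptor for SLIT proteins, and LBH, a transcription cofactor, were 3.64-fold, 3.64-fold and 3.61-fold lower.

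Inflammatory genes rose in groups. Of the 26 measured NF-kB targets and regulators 21 rose, 0 fell and 5 did not pass (22 rose adjusted over the list alone). Among them TNFAIP3, which ends NF-kB signalling, was 23.7-fold higher (4.57 ± 0.16), NFKBIA, its inhibitor in the cytoplasm, 6.12-fold, RELB, a subunit of the factor, 4.53-fold, TNFAIP2 4.39-fold and ICAM1, an adhesion molecule for leukocytes, 3.41-fold. Of 19 chemokines 9 rose and 10 did not pass (9 rose adjusted over the list alone), led by the neutrophil attractant CXCL8, 23.9-fold higher, CCL2, which attracts monocytes, 14.9-fold, CXCL11 9.62-fold, CCL5 6.79-fold and CCL20 4.64-fold. Of 18 cytokines and growth factors of inflammation 5 rose, IL6, IL32 (4.47-fold), CSF1 (2.34-fold), IL1B (2.23-fold) and IL15, while CSF3 fell and 12 did not pass (7 rose and 1 fell adjusted over the list alone). These 3 lists lay higher in camera (adjusted p = 2.9e-31, 1.3e-06 and 0.00012). None was called with the correlation taken from the arrays: adjusted p = 0.210, 0.248 and 0.263 with an estimated correlation, in the same order. Fry, which asks whether a list moves on balance one way, gave adjusted p = 0.000686, 0.0110 and 0.0116.

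Interferon and antigen presentation genes rose with TNF as well. Of 36 interferon response genes 33 rose, 0 fell and 3 did not pass (35 rose adjusted over the list alone), with a median log2 difference of 3.10. OAS1, a sensor of double-stranded RNA, was 28.7-fold higher (4.84 ± 0.37), IFI44 21.6-fold, MX1, an antiviral GTPase, 21.5-fold, EPSTI1 15.9-fold, the ubiquitin-like ISG15 14.3-fold and PARP14 4.89-fold. Of 18 antigen presentation genes 13 rose and 5 did not pass (16 rose and 1 fell adjusted over the list alone), among them the immunoproteasome subunit PSMB9 (6.69-fold), the peptide transporter subunit TAP1 (4.43-fold), HLA-F (3.94-fold) and TAPBP (2.23-fold). Both lists lay higher in camera (adjusted p = 7.6e-53 and 5.3e-19), and both had adjusted p = 0.210 with an estimated correlation. The interferon list differed between replicates more than the NF-kB list did: its mean was 9.57 ± 0.615 log2 (SD) with TNF, and the CTL arrays had 6.94 and 6.47.

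Camera also called 5 more lists higher with TNF. Of the 9 genes of the metallothionein list the 8 metallothioneins, which bind zinc and copper, rose and the zinc exporter SLC30A1 did not pass (8 rose adjusted over the list alone), among them MT1F 2.09-fold, MT1B 1.92-fold, MT1X 1.80-fold and MT2A 1.69-fold. The 8 metallothioneins share nearly identical sequence, so which of them changed is uncertain. Of 21 eicosanoid synthesis genes 4 rose, PTGS2 (8.51-fold), which makes prostaglandin H, PLA2G4A (5.78-fold), which releases arachidonic acid, PTGES (3.16-fold) and the prostaglandin E receptor PTGER2 (1.98-fold), and 17 did not pass (4 rose and 1 fell adjusted over the list alone). Of 8 AHR targets CYP1B1 (1.58 ± 0.16), AHR itself (2.20-fold) and NFE2L2 (1.85-fold) rose, and 5 did not pass, such as ALDH3A1 (-0.59 ± 0.18, adjusted p = 0.060; 3 rose and 1 fell adjusted over the list alone). The AHR median was 0.052, with 4 members above 0 and 4 below, and ranged from -0.033 without TNF replicate 2 to 0.43 with the filter at the median, the call being lost in both (adjusted p = 0.0549 and 0.0601). It was -0.022 with no filter (0.0567), 0.12 without CTL replicate 2 (0.0811) and 0.14 without TNF replicate 1, where the call was kept (0.0366). Of 20 matrix and wound genes SERPINE2 (2.47-fold), the collagenase MMP1 (1.47-fold) and tenascin TNC (1.36-fold) rose, the protease inhibitor TIMP3 (1.82-fold lower) and FN1 fell, and 15 did not pass (5 rose and 2 fell adjusted over the list alone). Of 39 cell cycle genes 0 changed by limma over all genes or adjusted over the list alone, and their median was 0.10; ASPM (0.51 ± 0.15, adjusted p = 0.055), CDC6 (0.65 ± 0.23), AURKB (0.51 ± 0.18) and CDK1 (0.53 ± 0.19) had the smallest p. For these 5 lists camera gave adjusted p = 9.8e-10, 0.029, 0.050, 0.030 and 0.037, in the order given. Each call was lost otherwise, at adjusted p = 0.252, 0.310, 0.286, 0.243 and 0.570 with an estimated correlation.

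**Figure D2:**
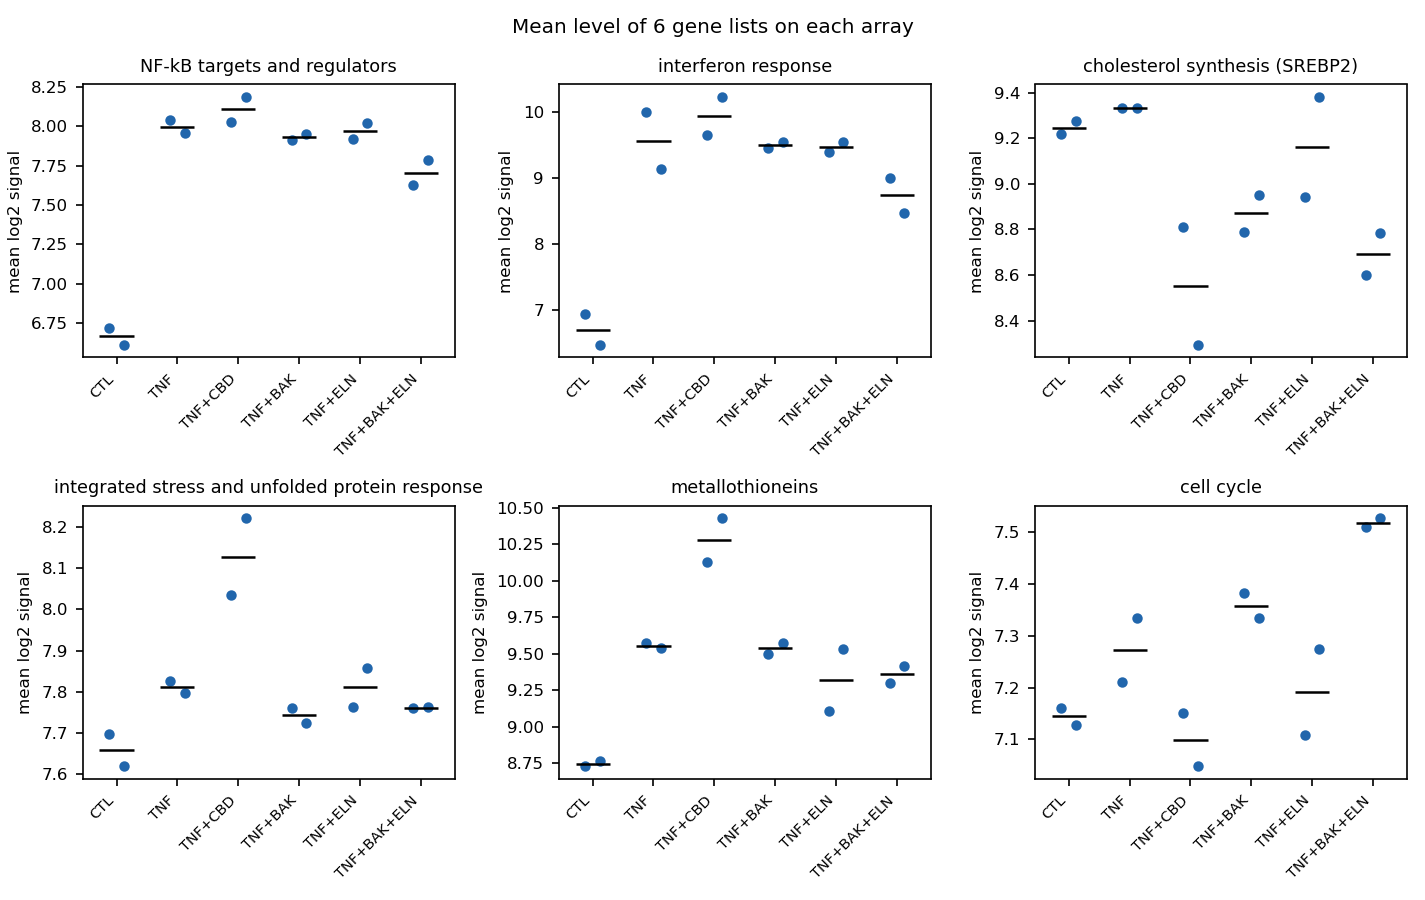
Mean log2 signal of the measured genes of 6 lists on each array (points; bars are group means) in the 6 groups of 2 arrays. NF-kB and interferon genes lie lowest on the CTL arrays, the metallothionein list highest on the TNF+CBD arrays, and cholesterol synthesis genes below both TNF arrays (9.33) on both arrays of TNF+CBD, TNF+BAK and TNF+BAK+ELN, and also on both CTL arrays (9.22 and 9.28) and TNF+ELN replicate 1 (8.94).

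Fewer genes passed in TNF against CTL when any of its 4 arrays was left out. limma called 892 genes without CTL replicate 1, 748 without CTL replicate 2, 559 without TNF replicate 1 and 775 without TNF replicate 2, and 1932 with TNF+ELN replicate 1 left out of the fit. Of the 10 list calls 6 were kept without each of the 4 arrays in turn, but 2 of their medians moved: that of chemokines (0.40) was 0.20 without TNF replicate 1 and 0.76 without TNF replicate 2, and that of cytokines (0.29) was 0.087 without CTL replicate 1, 0.46 without CTL replicate 2 and 0.0054 without TNF replicate 1. The matrix, cell cycle and AHR lists were lost without CTL replicate 1 (adjusted p = 0.0799, 0.0527 and 0.0622), CTL replicate 2 (0.0550, 0.0988 and 0.0811) or TNF replicate 2 (0.0545, 0.295 and 0.0549), and the eicosanoid list without CTL replicate 1 (0.0870) or TNF replicate 1 (0.0804). Changes of processing ended the matrix call too (0.0754 after cyclic loess), the eicosanoid call (0.139 with no filter, 0.0744 with the filter at the median) and the AHR call (0.0590 with arrays centred on their medians, 0.0734 after cyclic loess, 0.0582 with the replicate block, 0.0802 with TNF+ELN replicate 1 left out and 0.0726 with that group left out). PTGER2 did not pass without CTL replicate 1 (0.74, adjusted p = 0.0851) or TNF replicate 1 (0.87, 0.0981). TIMP3 did not pass without CTL replicate 1 (-0.84, 0.0687), CTL replicate 2 (-0.89, 0.0583) or TNF replicate 2 (-0.71, 0.112), nor did TNC without CTL replicate 2 (0.42, 0.0875), TNF replicate 1 (0.46, 0.0778) or TNF replicate 2 (0.43, 0.0796).

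The next comparisons asked what each compound did in cells given TNF. TNF+CBD against TNF changed 2 genes. At an unadjusted p under 0.05 were 698, against 662 by chance, or 1131 with the TNF+ELN group left out of the fit. SLC3A2, the heavy chain of amino acid transporters, rose 2.59-fold (1.37 ± 0.14, adjusted p = 0.0019), from 10.12 ± 0.05 to 11.49 ± 0.19 log2 (SD). TMEM97, a sterol-related membrane protein known as the sigma-2 receptor, was 2.58-fold lower (-1.37 ± 0.14, adjusted p = 0.0019). Next by p were MT1L (0.85 ± 0.12, adjusted p = 0.050), MEDAG (1.17 ± 0.18, 0.072), DHCR7, the last enzyme of cholesterol synthesis (-1.37 ± 0.22, 0.082), and the fatty acid carrier FABP3 (-1.71 ± 0.27, 0.082), which did not pass. Without TNF replicate 2 or TNF+CBD replicate 2 limma called 0 genes: SLC3A2 was at 1.41 and TMEM97 at -1.32 without the first (adjusted p = 0.0802 for each), and at 1.24 and -1.24 without the second (0.0809 for each). Without TNF+CBD replicate 1 it called 28. With TNF+ELN replicate 1 left out of the fit it called 44.

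Camera called 4 lists of lipid, stress and metal-related genes with CBD, in which limma called 2 members. All 23 measured cholesterol synthesis genes had a value below 0 with a median of -0.83; 0 passed by limma over all genes and 16 fell adjusted over the list alone. HMGCS1, an early enzyme of the pathway, was at -1.67 ± 0.28 (adjusted p = 0.090), ERG28 at -1.02 ± 0.19 and NSDHL at -0.85 ± 0.16. In the list of fatty acid synthesis and LXR targets TMEM97 fell and 16 of 17 did not pass (2 rose and 9 fell adjusted over the list alone), with FADS2, a desaturase, at -0.89 ± 0.16, ACSS2 at -0.98 ± 0.19 and SCD at -1.0 ± 0.20. In the integrated stress and unfolded protein response SLC3A2 rose and 31 of 32 did not pass (8 rose adjusted over the list alone); its partner in amino acid transport SLC7A5 was at 1.18 ± 0.20 (adjusted p = 0.095), the stress factor ATF3 at 1.43 ± 0.35 and the chaperone cofactor DNAJB9 at 0.63 ± 0.17. All 9 genes of the metallothionein list had a value above 0 with a median of 0.74; 0 passed by limma over all genes and 8 rose adjusted over the list alone, with MT1X at 0.74 ± 0.13, MT1F at 1.00 ± 0.18, MT1E at 0.76 ± 0.14 and MT1M at 0.96 ± 0.20. Camera called the first 2 lists lower (adjusted p = 2.6e-31 and 2.3e-08) and the other 2 higher (1.4e-11 and 3.0e-19). The values were adjusted p = 0.210, 0.243, 0.210 and 0.210 with an estimated correlation. Without TNF+CBD replicate 2 the medians of the first 2 lists, -0.83 and -0.44, were -0.53 and -0.25.

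Camera called 5 more lists in TNF+CBD against TNF, of which limma called 0 members over all genes. EGFR ligands and immediate early genes lay higher (median 0.20 over 26, 6 rose adjusted over the list alone), with the phosphatases DUSP5 at 0.99 ± 0.22 and DUSP6 at 0.82 ± 0.20, EREG, an EGFR ligand, at 1.15 ± 0.29 and JUN at 0.65 ± 0.18. NRF2 targets lay higher (0.17 over 29, 0 alone), with ABCC3 at 0.46 ± 0.17 and PGD at 0.38 ± 0.15 but ME1 at -0.30 ± 0.13, as did heat shock genes (0.14 over 14, 1 rose alone), with HSPH1 at 0.44 ± 0.12. Cell cycle genes lay lower (-0.18 over 39, 0 alone), with ASPM at -0.52 ± 0.15, TPX2 at -0.41 ± 0.12 and NUSAP1 at -0.39 ± 0.14. The interferon list lay higher (0.27 over 36, 0 alone), with RSAD2 at 1.41 ± 0.47 and IFIT2 at 1.31 ± 0.50, but its median was -0.12 without TNF replicate 2 and 0.026 without TNF+CBD replicate 2, and the call was lost in both (adjusted p = 0.145 and 0.743). Camera gave adjusted p = 6.6e-07, 0.0020, 0.018, 3.3e-06 and 1.2e-05. In the same order these were adjusted p = 0.219, 0.243, 0.376, 0.243 and 0.623 with an estimated correlation. The EGFR median was 0.12 without TNF+CBD replicate 2. NRF2 targets lost their call without TNF+CBD replicate 2 (0.0818), and heat shock genes without TNF+CBD replicate 2 (0.181) or TNF replicate 1 (0.0804).

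TNF+BAK against TNF changed 0 genes by limma. At an unadjusted p under 0.05 were 216, where chance gives 662, or 377 with the TNF+ELN group left out of the fit. The smallest p belonged to NTN4, a laminin-related netrin (0.63 ± 0.17), ADHFE1 (0.64 ± 0.18) and GGA1 (0.47 ± 0.14) above 0, and to TMEM97 (-0.63 ± 0.14), RAB33A (-0.78 ± 0.17) and MAP2 (-0.69 ± 0.15) below 0, all at an adjusted p of 1.00. Cholesterol synthesis genes lay lower as a list: 21 of 23 had a value below 0, the median was -0.46, and 9 fell adjusted over the list alone. HMGCS1 was at -0.96 ± 0.28, DHCR7 at -0.76 ± 0.22, CYP51A1, a sterol demethylase, at -0.66 ± 0.18 and NSDHL at -0.55 ± 0.16. Fatty acid synthesis and LXR targets lay lower (median -0.21 over 17, 1 fell alone), with the elongase ELOVL6 at -0.49 ± 0.15, FADS2 at -0.47 ± 0.16 and SCD at -0.52 ± 0.20. NRF2 targets lay lower (-0.10 over 29, 0 alone), with the haem oxygenase HMOX1 at -0.68 ± 0.18, NFE2L2, which encodes NRF2, at -0.48 ± 0.14, and TXNRD1 at -0.32 ± 0.14. Integrated stress genes lay lower (-0.052 over 32, 0 alone), with DDIT4 at -0.31 ± 0.14 and HERPUD1 at -0.26 ± 0.13, and EGFR ligands and immediate early genes higher (0.096 over 26, 0 alone), with HBEGF, an EGFR ligand, at 0.50 ± 0.16, MYC at 0.51 ± 0.18 and EGFR at 0.30 ± 0.12. Camera gave these 5 lists adjusted p = 5.2e-24, 3.4e-08, 0.0039, 0.035 and 0.0058. The same lists had adjusted p = 0.228, 0.243, 0.257, 0.570 and 0.415 with an estimated correlation. The cholesterol and fatty acid calls were kept without each array in turn. NRF2 targets were lost without TNF replicate 2 (0.0540) or TNF+BAK replicate 2 (0.131, with the median at 0.016), stress genes without TNF replicate 1 (0.251) or TNF+BAK replicate 2 (0.235), and the EGFR list without TNF replicate 2 (0.0972) or TNF+BAK replicate 1 (0.106). The stress call was also lost with the filter at the median (0.152) or after cyclic loess (0.0524). A fit of the compared groups alone called 17 genes.

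TNF+ELN against TNF changed 0 genes by limma (878 at an unadjusted p under 0.05, smallest adjusted p 0.694). MTIF3, a mitochondrial initiation factor (0.62 ± 0.14), IFT56 (0.56 ± 0.13) and WDPCP (0.75 ± 0.18), proteins of cilia, had the smallest p above 0, and PPP1R12B (-1.06 ± 0.24), the kinesin KIF3C (-0.53 ± 0.13) and NAT10 (-0.61 ± 0.16) below 0. Metallothioneins lay lower as a list (median -0.29 over 9, 0 adjusted over the list alone), with MT2A at -0.37 ± 0.14, MT1X at -0.30 ± 0.13, MT1F at -0.38 ± 0.18 and MT1B at -0.27 ± 0.15. p53 targets lay lower (-0.13 over 17, 0 alone), with the repair factor XPC at -0.54 ± 0.24, GADD45A at -0.56 ± 0.27, TIGAR at -0.52 ± 0.28 and MDM2, the ligase for p53, at -0.42 ± 0.23. Camera gave adjusted p = 0.0023 and 0.050. These became adjusted p = 0.570 and 0.574 with an estimated correlation. Both calls rested on the array that stood apart: without TNF+ELN replicate 1 the medians were -0.0085 and -0.00059 (adjusted p = 0.561 and 0.999), and GADD45A was at 0.021. The p53 call was also lost without TNF replicate 1 (0.0733) or TNF replicate 2 (0.0999), with the filter at the median (0.153), arrays centred on their medians (0.0517), cyclic loess (0.0539) or the replicate block (0.0505). limma called 0 genes without TNF+ELN replicate 1 and 1984 without TNF+ELN replicate 2, where replicate 1 stands alone for its group.

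TNF+BAK+ELN against TNF, which asks what the combination did, changed 0 genes by limma. At an unadjusted p under 0.05 were 687 (smallest adjusted p 0.306), or 1133 with the TNF+ELN group left out of the fit (0.058). NTN4 (1.04 ± 0.17), RHOBTB3 (0.92 ± 0.16) and CREG1 (1.02 ± 0.19) had the smallest p above 0. ACSS2, which makes acetyl-CoA from acetate (-1.05 ± 0.19), TNFAIP6 (-0.56 ± 0.10) and HMGCS1 (-1.48 ± 0.28) had the smallest below 0, all at an adjusted p of 0.31. All 26 NF-kB genes had a value below 0 with a median of -0.30 (0 adjusted over the list alone): the adhesion molecule VCAM1 was at -0.79 ± 0.25, the subunits REL and RELA at -0.62 ± 0.20 and -0.43 ± 0.15, and TRAF1 at -0.46 ± 0.17. All 36 interferon genes had a value below 0 with a median of -0.84 (21 fell adjusted over the list alone), among them MX1 at -1.24 ± 0.32, IFI44L at -1.37 ± 0.35, IFI6 at -0.86 ± 0.23 and PARP14 at -0.63 ± 0.15. Antigen presentation genes lay lower (-0.30 over 18, 0 alone), with TAP1 at -0.60 ± 0.19, HLA-E at -0.40 ± 0.15 and HLA-F at -0.40 ± 0.15. Camera called these 3 lists lower (adjusted p = 2.1e-11, 5.9e-32 and 3.1e-08). They had adjusted p = 0.219, 0.243 and 0.243 with an estimated correlation. The interferon median was -0.40 without TNF replicate 1, -1.27 without TNF replicate 2 and -0.53 without TNF+BAK+ELN replicate 2, the antigen presentation median -0.14 without TNF replicate 1, and the NF-kB median -0.18 without TNF+BAK+ELN replicate 1.

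Lipid genes lay lower with the combination too. Cholesterol synthesis genes had a median of -0.69, with 21 of 23 below 0 and 16 that fell adjusted over the list alone, CYP51A1 being at -0.89 ± 0.18, the sterol sensor INSIG1 at -0.73 ± 0.15 and STARD4 at -0.64 ± 0.14. Fatty acid synthesis and LXR targets had a median of -0.41 over 17 (10 fell alone), with TMEM97 at -0.72 ± 0.14, ELOVL7 at -0.75 ± 0.16 and SCD at -0.89 ± 0.20. NRF2 targets lay lower (-0.070 over 29, 2 fell alone), with HMOX1 at -0.93 ± 0.18 and NFE2L2 at -0.57 ± 0.14, and so did metallothioneins (-0.20 over 9, 0 alone), with MT1M at -0.34 ± 0.20. Cell cycle genes lay higher (0.22 over 39, 0 alone), with DLGAP5 at 0.57 ± 0.17, HMMR at 0.48 ± 0.15, KIF11, a mitotic kinesin, at 0.44 ± 0.15 and CDC6 at 0.63 ± 0.23. Camera gave these 5 lists adjusted p = 5.5e-25, 6.9e-14, 0.0016, 0.0038 and 1.8e-08. In that order they had adjusted p = 0.219, 0.210, 0.243, 0.574 and 0.219 with an estimated correlation. For the fatty acid list fry gave adjusted p = 0.0443. Of the 8 calls 7 were kept without each array in turn, and the metallothionein call was lost without TNF+BAK+ELN replicate 1 (0.154). limma called 24 genes in a fit of the compared groups alone and 21 with array weights.

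**Figure D3:**
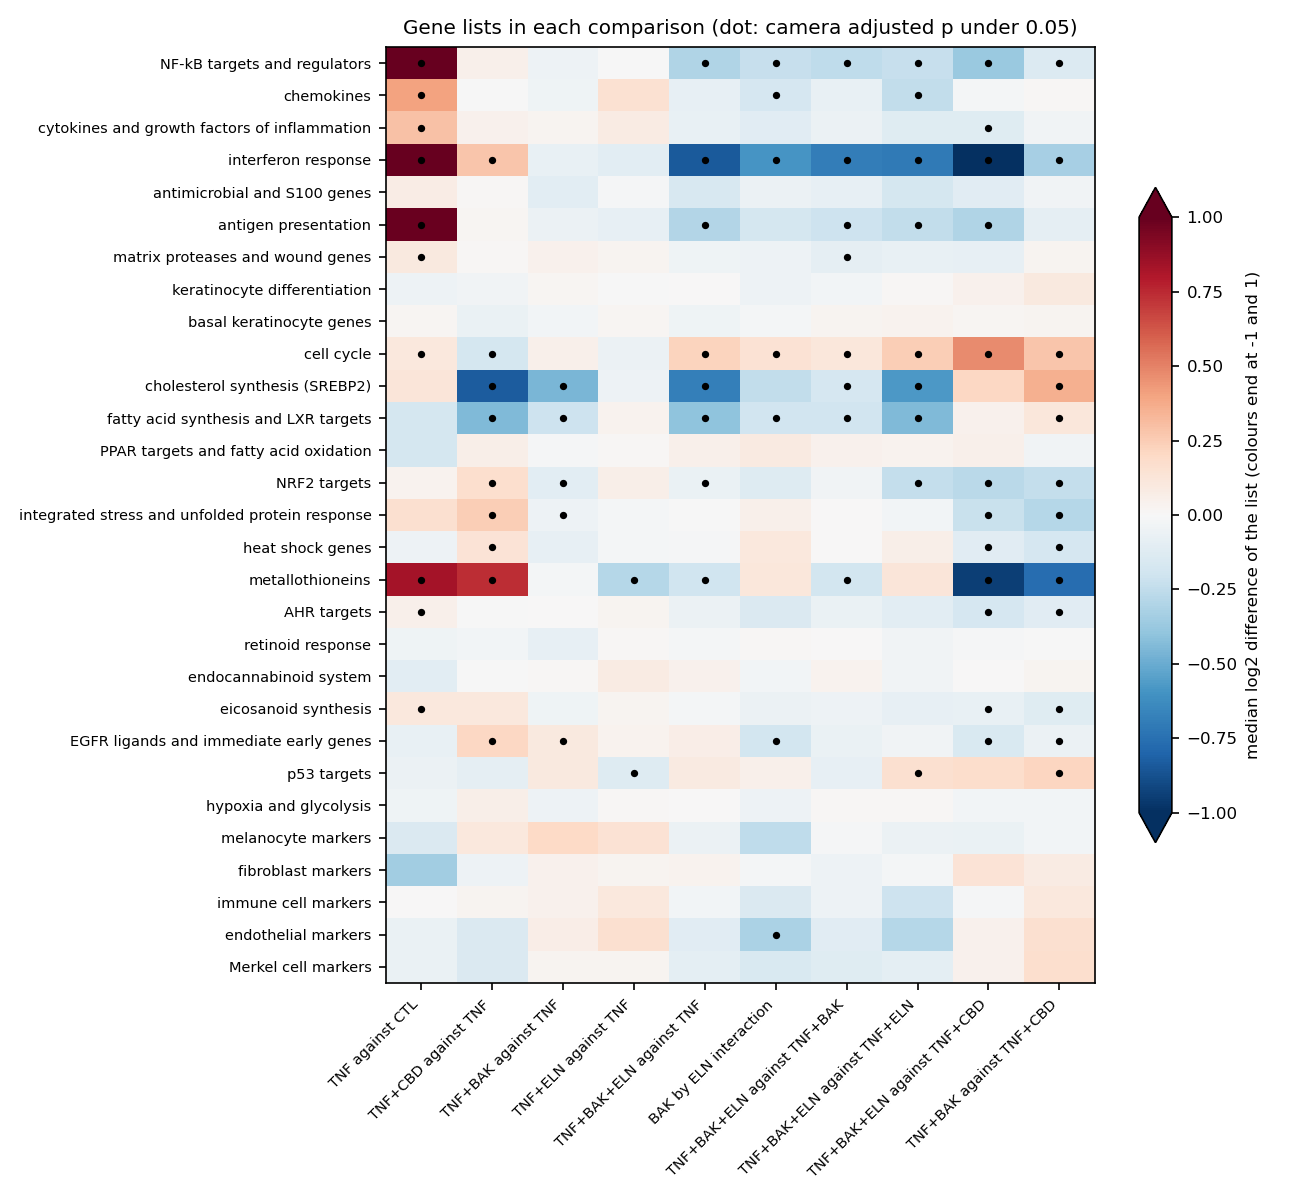
Median log2 difference of 29 gene lists (vertical axis) in 10 comparisons (horizontal axis); colours end at -1 and 1, and a dot marks a camera adjusted p under 0.05 with a preset correlation of 0.01. No list was called with an estimated correlation, where the smallest adjusted p was 0.210.

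The interaction asks whether the combination differed from the sum of the effects of BAK and ELN, at the doses used. The labels do not say whether BAK and ELN had the same doses in the mixture as alone. The sum therefore need not be the value without an interaction. The interaction changed 0 genes by limma (595 at an unadjusted p under 0.05, smallest adjusted p 0.877). FANCM, a DNA repair helicase (1.1 ± 0.25), ADSS1 (1.17 ± 0.29) and KBTBD3 (0.93 ± 0.25) had the smallest p above 0, and MON1A (-0.92 ± 0.19), VMO1 (-0.81 ± 0.20) and ELOVL7 (-0.88 ± 0.22) below 0. NF-kB genes lay lower than the sum of effects (median -0.23 over 26, 0 adjusted over the list alone), with NFKBIA at -0.57 ± 0.19, IER3 at -0.45 ± 0.19, RELB at -0.41 ± 0.22 and TNFAIP3 at -0.41 ± 0.23. Chemokines lay lower (-0.17 over 19, 0 alone), with CCL5 at -0.87 ± 0.34, CCL7 at -0.54 ± 0.25 and CCL2 at -0.48 ± 0.23, and so did interferon genes (-0.59 over 36, 0 alone), with CMPK2 at -1.63 ± 0.50, PARP9 at -0.96 ± 0.36 and ISG15 at -1.0 ± 0.39. Camera gave adjusted p = 0.0029, 0.018 and 2.2e-10. They were adjusted p = 0.517, 0.568 and 0.547 with an estimated correlation.

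Of the other lists in the interaction, fatty acid synthesis and LXR targets lay lower (-0.19 over 17, 1 fell adjusted over the list alone), with ACSS2 at -0.51 ± 0.27, and so did EGFR ligands and immediate early genes (-0.19 over 26, 0 alone), with HBEGF at -0.59 ± 0.23 and EGR1 at -0.47 ± 0.25. Endothelial markers lay lower (-0.32 over 6, 0 alone), with the junction protein ESAM at -0.46 ± 0.23 and the VEGF receptor KDR at -0.42 ± 0.21, and cell cycle genes higher (0.15 over 39, 0 alone), with CDK1 at 0.91 ± 0.27, NDC80 at 1.17 ± 0.41 and TYMS at 0.91 ± 0.35. Camera gave adjusted p = 0.0083, 0.020, 0.050 and 0.00015. They were adjusted p = 0.547, 0.505, 0.503 and 0.310 with an estimated correlation. The interferon and cell cycle calls were kept without each of the 8 arrays in turn, but the interferon median was -0.16 without TNF replicate 2 (adjusted p = 0.0245), -1.12 without TNF replicate 1 and -0.32 without TNF+BAK+ELN replicate 2, and the cell cycle median 0.23 without TNF replicate 1. The other 5 calls were lost without at least 1 array. Without TNF+ELN replicate 2 these 5 had adjusted p = 0.0807 to 0.201, and limma then called 1256 genes. Without TNF+BAK+ELN replicate 1 the NF-kB, chemokine, fatty acid and EGFR lists had 0.214, 0.183, 0.126 and 0.0507, and without TNF+BAK replicate 1 the chemokine and EGFR lists 0.0557 and 0.0982. The chemokine call was lost without TNF replicate 2 (0.217) and the fatty acid call without TNF+BAK replicate 2 (0.213). The endothelial call was lost without 7 of the 8 arrays (0.0583 to 0.220), TNF+BAK+ELN replicate 1 being the exception, and with no filter (0.391), arrays centred on their medians (0.0501) or cyclic loess (0.0598). The EGFR call was lost with the filter at the median (0.0726).

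Further comparisons set the combination against each of its parts, at doses that the labels do not give. TNF+BAK+ELN against TNF+BAK changed 0 genes by limma (412 at an unadjusted p under 0.05, or 759 with the TNF+ELN group left out of the fit), and 29 in a fit of these groups alone. CREG1 (0.97 ± 0.19), the cation channel NALCN (0.73 ± 0.15) and ERRFI1 (0.70 ± 0.15) had the smallest p above 0, and PARP14 (-0.67 ± 0.15), PGLYRP4 (-0.68 ± 0.16) and WDR6 (-0.50 ± 0.13) below 0. All 36 interferon genes had a value below 0 (median -0.69, 12 fell adjusted over the list alone), with MX1 at -1.22 ± 0.32, ISG15 at -0.97 ± 0.28 and IFI44L at -1.18 ± 0.35, and so had all 26 NF-kB genes (-0.25, 0 alone), with IER3 at -0.37 ± 0.13 and TNFAIP2 at -0.32 ± 0.14. Antigen presentation genes lay lower (-0.20 over 18, 0 alone), with TAPBP at -0.32 ± 0.11, and cell cycle genes higher (0.11 over 39, 0 alone), with DLGAP5 at 0.64 ± 0.17. In camera these had adjusted p = 3.3e-31, 6.5e-09, 1.5e-06 and 1.4e-05, and kept these calls without each array in turn, with the NF-kB median at -0.15 without TNF+BAK+ELN replicate 1. They had adjusted p = 0.248, 0.243, 0.288 and 0.255 with an estimated correlation. Cholesterol synthesis genes (-0.16, with LSS at -0.40 ± 0.16), fatty acid synthesis and LXR targets (-0.19, with ABCA1, a cholesterol exporter, at -0.36 ± 0.12), metallothioneins (-0.18, with MT1G at -0.21 ± 0.18) and matrix genes (-0.088, with the gelatinase MMP2 at -0.18 ± 0.09) lay lower, with 0 members adjusted over each list alone. By camera the values were adjusted p = 0.00077, 8.0e-05, 0.0044 and 0.050. They had adjusted p = 0.611, 0.375, 0.574 and 0.255 with an estimated correlation, and all 4 calls were lost without TNF+BAK+ELN replicate 1 (0.321, 0.0506, 0.219 and 0.0764) or TNF+BAK replicate 2 (0.127, 0.104, 0.0596 and 0.0802). The matrix call was also lost without TNF+BAK replicate 1 (0.133) or TNF+BAK+ELN replicate 2 (0.229), with arrays centred on their medians (0.0513) or with the replicate block (0.0519).

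TNF+BAK+ELN against TNF+ELN changed 0 genes by limma (1690 at an unadjusted p under 0.05, smallest adjusted p 0.103), in a comparison that holds the array that stood apart. FANCM (1.15 ± 0.18), the calcium-binding S100A2 (0.99 ± 0.16) and DTL (0.97 ± 0.16) had the smallest p above 0, and ELOVL7 (-1.14 ± 0.16), TMEM97 (-0.87 ± 0.14) and the amino acid transporter SLC7A8 (-0.64 ± 0.10) below 0. Interferon genes lay lower (median -0.71, 36 of 36 below 0, 15 fell adjusted over the list alone), with CMPK2 at -1.67 ± 0.36, OAS1 at -1.34 ± 0.37 and MX2 at -1.22 ± 0.34. NF-kB genes (-0.23, 5 fell alone) included NFKBIA at -0.61 ± 0.13, chemokines (-0.25, 1 fell alone) CXCL8 at -0.83 ± 0.27, and antigen presentation genes (-0.24, 0 alone) ERAP2 at -0.52 ± 0.19. Cholesterol synthesis genes lay lower (-0.58, 1 rose and 14 fell alone), with INSIG1 at -0.95 ± 0.15 and DHCR7 at -1.0 ± 0.22, as did fatty acid synthesis and LXR targets (-0.44, 11 fell alone) and NRF2 targets (-0.24, 6 fell alone), with HMOX1 at -0.98 ± 0.18 and CBR1 at -0.57 ± 0.16. Cell cycle genes lay higher (0.24, 5 rose alone), with the DNA clamp PCNA at 1.08 ± 0.25 and TYMS at 1.2 ± 0.25, and so did p53 targets (0.16, 2 rose and 1 fell alone), with TIGAR at 1.13 ± 0.28 and PLK3 at -0.43 ± 0.13. Camera gave these 9 lists adjusted p from 8.2e-15 (interferon) to 0.050 (p53). In the order named they had adjusted p = 0.50, 0.322, 0.503, 0.518, 0.415, 0.243, 0.255, 0.230 and 0.574 with an estimated correlation. Without TNF+ELN replicate 1 the p53 call was lost (0.495), and without TNF+ELN replicate 2 the antigen presentation, cholesterol and NRF2 calls were (0.280, 0.0595 and 0.201), with 2291 genes called by limma. Without TNF+BAK+ELN replicate 1 the chemokine and p53 calls were lost (0.0904 and 0.253), and the NF-kB and NRF2 medians were -0.14 and -0.11. Without TNF+BAK+ELN replicate 2 the NF-kB and interferon medians were -0.37 and -0.40. The p53 call was also lost with the filter at the median (0.122), after cyclic loess (0.0588) or with the replicate block (0.05002).

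CBD served as a second compound for reference, so the combination and BAK were each set against it. TNF+BAK+ELN against TNF+CBD changed 36 genes, 9 of which were higher and 27 lower with the combination (1384 at an unadjusted p under 0.05). RSAD2, an antiviral enzyme, was 7.32-fold lower (-2.87 ± 0.47, adjusted p = 0.032), ATF3 4.39-fold, EREG 3.48-fold and SLC3A2 2.93-fold lower (-1.55 ± 0.14, adjusted p = 0.00090). HSPA4L, a heat shock protein, was 2.57-fold higher (1.36 ± 0.24, adjusted p = 0.041), GALNT14, an enzyme of protein glycosylation, 2.41-fold, the tropomyosin TPM1 2.14-fold and MKX, a transcription factor of tendon, 2.14-fold. Here fell and rose mean lower and higher than with TNF+CBD. Means of the integrated stress list were 8.13 log2 with TNF+CBD, 7.81 with TNF and 7.76 with the combination. In the same order the metallothionein list had 10.28, 9.56 and 9.36, heat shock genes 9.30, 9.16 and 9.16, and interferon genes 9.94, 9.57 and 8.74. In the integrated stress list 5 of 32 fell (11 adjusted over the list alone), SLC3A2, ATF3, DNAJB9 (2.33-fold), SLC7A5 (2.61-fold) and DDIT3, a stress-induced factor (2.17-fold). In the metallothionein list 5 of 9 fell (9 alone), the metallothioneins MT1M (2.46-fold), MT1F (2.38-fold), MT1E (1.96-fold) and MT1X (1.92-fold) and the zinc exporter SLC30A1 (2.12-fold). HMOX1 fell 2.08-fold among 29 NRF2 targets (6 alone), and PTGER2 and PTGS2 fell 2.28-fold and 2.21-fold among 21 eicosanoid genes (3 alone). KIF11 rose 1.79-fold among 39 cell cycle genes (19 rose alone, median 0.47). RSAD2 was the member to fall among 36 interferon genes, all of which had a value below 0 (34 fell alone, median -1.12), EREG among 26 EGFR and immediate early genes (5 alone) and SLC7A5 among 8 AHR targets (3 alone). NF-kB genes (median -0.37, 11 fell alone), antigen presentation genes (-0.30, 8 alone), cytokines (-0.12, 4 alone) and heat shock genes (-0.11, 2 alone) had 0 members past the limma threshold, with BCL2A1 at -0.89 ± 0.19, TAP1 at -1.01 ± 0.19, IL24 at -1.11 ± 0.22 and HSPA1A at -0.43 ± 0.13.

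Camera called these 12 lists in TNF+BAK+ELN against TNF+CBD, the cell cycle list higher and the others lower, with adjusted p from 4.8e-35 (interferon) to 0.049 (heat shock). The NF-kB, cell cycle, NRF2, integrated stress and metallothionein lists had adjusted p = 0.210 with an estimated correlation, the interferon list 0.243, AHR targets 0.230, antigen presentation and EGFR genes 0.288, eicosanoid genes 0.310, heat shock genes 0.50 and cytokines 0.503. Fry called the cell cycle list (adjusted p = 0.0179), NRF2 targets (0.0209), metallothioneins (0.0213), integrated stress genes (0.0246), NF-kB genes (0.0416) and AHR targets (0.0105). limma called 1 gene without TNF+CBD replicate 2 or TNF+BAK+ELN replicate 1, 9 without TNF+BAK+ELN replicate 2 and 68 without TNF+CBD replicate 1, and 302 with TNF+ELN replicate 1 left out of the fit. Without TNF+CBD replicate 2 the cytokine, heat shock and EGFR lists lost their call (0.0877, 0.245 and 0.0628), without TNF+BAK+ELN replicate 2 the heat shock list (0.226), and without TNF+CBD replicate 1 or TNF+BAK+ELN replicate 1 the eicosanoid list (0.0968 and 0.102). Processing ended calls too: with the filter at the median the cytokine list (0.537, median -0.026), the heat shock list (0.0698) and AHR targets (0.0744), the heat shock list also after cyclic loess (0.0886) and with the replicate block (0.0545), and the eicosanoid list with no filter (0.135) or with TNF+ELN replicate 1 left out (0.0522). Of the genes named here SLC3A2 alone passed without TNF+CBD replicate 2 or TNF+BAK+ELN replicate 1. With the replicate block RSAD2 (adjusted p = 0.0519), ATF3 (0.0519), TPM1 (0.0522) and PTGER2 (0.0602) did not pass. KIF11 did not pass with no filter (adjusted p = 0.0502), arrays centred on their medians (0.0503), cyclic loess (0.0558), the replicate block (0.0519) or without any of the 4 arrays in turn (0.0869 to 0.535). HSPA4L did not pass after cyclic loess (0.0628) or with the replicate block (0.0663), nor without TNF+CBD replicate 2 (0.641), TNF+BAK+ELN replicate 1 (0.305) or TNF+BAK+ELN replicate 2 (0.199). CRYAB, a heat shock member at 0.25 ± 0.17, was at -0.042 without TNF+BAK+ELN replicate 1.

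BAK and CBD are both plant phenols that carry a terpene part, and the labels give the dose of neither, so their readouts stand side by side at unknown doses. TNF+BAK against TNF+CBD changed 1 gene (863 at an unadjusted p under 0.05): SLC3A2 was 2.74-fold lower with BAK (-1.45 ± 0.14, adjusted p = 0.0019). Next by p were SLC7A5 (-1.38 ± 0.20, adjusted p = 0.063), MT1L (-0.86 ± 0.12, 0.062), HSPA4L (1.52 ± 0.24, 0.092), NTM (0.80 ± 0.14, 0.11) and TMEM97 (0.73 ± 0.14, 0.12), which did not pass. Integrated stress genes lay lower with BAK (median -0.28, 9 fell adjusted over the list alone), as did metallothioneins (-0.76, 8 alone), with MT1F at -1.05 ± 0.18, NRF2 targets (-0.24, 2 alone), with HMOX1 at -0.81 ± 0.18, and heat shock genes (-0.17, 2 alone), with HSPH1 at -0.43 ± 0.12. Cell cycle genes lay higher (0.28, 0 alone), with MKI67, a marker of cycling cells, at 0.42 ± 0.14. The camera test gave adjusted p = 2.5e-14, 1.3e-17, 1.3e-07, 0.0012 and 2.2e-09, and kept these 5 calls without each array in turn, with the stress median at -0.18 without TNF+CBD replicate 2. They had adjusted p = 0.210, 0.210, 0.210, 0.243 and 0.210 with an estimated correlation. For a gene of median precision that did not pass, the 95% interval of the difference reaches 0.356 log2 to either side of its own value. This is no upper bound on the differences left open between the compounds, since SLC7A5 and HSPA4L did not pass at -1.38 and 1.52. limma called 0 genes without TNF+CBD replicate 2 or TNF+BAK replicate 2, 12 without TNF+CBD replicate 1, and 61 with TNF+ELN replicate 1 left out of the fit.

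Camera called 8 more lists between BAK and CBD, each of which was lost without at least 1 array. Cholesterol synthesis genes (0.35, 0 alone) and fatty acid synthesis and LXR targets (0.11, 4 rose and 1 fell alone) lay higher with BAK, with MVK at 0.73 ± 0.26 and PNPLA3 at 0.47 ± 0.13, and so did p53 targets (0.21, 0 alone), with SESN1 at 0.64 ± 0.18. Lower with BAK were interferon genes (-0.33, 0 alone), with OASL at -1.14 ± 0.40, NF-kB genes (-0.13, 1 alone), with TNIP3 at -0.72 ± 0.21, AHR targets (-0.11, 3 alone), with CYP1B1 at -0.53 ± 0.16, eicosanoid genes (-0.12, 1 rose and 3 fell alone), with PLA2G4A at -0.99 ± 0.25, and EGFR and immediate early genes (-0.056, 1 rose and 3 fell alone), with JUNB at -0.81 ± 0.19. These lists had camera adjusted p = 2.4e-06, 0.030, 0.0039, 5.1e-08, 0.0023, 0.022, 0.040 and 0.022. They had adjusted p = 0.530, 0.581, 0.493, 0.574, 0.517, 0.243, 0.350 and 0.514 with an estimated correlation, in the order named. Medians moved with single arrays. The cholesterol median was 0.10 without TNF+CBD replicate 2 and 0.645 without TNF+CBD replicate 1, and the interferon median -0.083 and -0.60. That of NF-kB genes was -0.033 without TNF+CBD replicate 2, and the fatty acid median 0.30 without TNF+CBD replicate 1. Without TNF+CBD replicate 2 the cholesterol, fatty acid, interferon, NF-kB and EGFR lists had adjusted p = 0.493, 0.575, 0.174, 0.183 and 0.599, the fatty acid and EGFR medians turning to -0.016 and 0.018. Without TNF+BAK replicate 1 the AHR, eicosanoid and p53 lists had 0.0732, 0.0852 and 0.0732. Without TNF+BAK replicate 2 the fatty acid and EGFR lists had 0.556 and 0.130, and without TNF+CBD replicate 1 the eicosanoid and p53 lists 0.129 and 0.0550. The AHR call was also lost with the filter at the median (0.348, median -0.064), and the eicosanoid call with no filter (0.272, the median turning to 0.0028), with arrays centred on their medians (0.0501), with TNF+ELN replicate 1 left out (0.103) or with that group left out (0.0940).

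Since the series title names endocannabinoid tone, genes of that system were followed in every comparison. Of 28 measured members TNF raised MGLL, the lipase that breaks down 2-arachidonoylglycerol, 1.96-fold (0.97 ± 0.17, adjusted p = 0.0031), and PTGS2, lowered the phosphodiesterase GDPD1 1.72-fold (-0.78 ± 0.19), and left 25 that did not pass (the same counts adjusted over the list alone). FAAH, which breaks down anandamide, was at -0.11 ± 0.15, NAPEPLD, which makes it, at -0.31 ± 0.38, the lipases DAGLA and DAGLB at -0.18 ± 0.15 and -0.36 ± 0.13, the receptors CNR1 and CNR2 at -0.21 ± 0.17 and -0.33 ± 0.17, and TRPV1 at 0.005 ± 0.19. In TNF+BAK+ELN against TNF, FAAH was at -0.17 ± 0.15, MGLL at -0.08 ± 0.17, NAPEPLD at 0.42 ± 0.38, CNR1 at 0.00 ± 0.17 and the fatty acid carrier FABP5 at 0.45 ± 0.23, and none of them passed. In the interaction FAAH was at -0.53 ± 0.21, CNR2 at -0.57 ± 0.24, FABP5 at 0.62 ± 0.32 and NAPEPLD at 0.69 ± 0.53 (adjusted p = 0.88 for each). The list was called in 0 of the 10 comparisons by camera (smallest adjusted p 0.252, in TNF+ELN against TNF). PTGS2 in TNF+BAK+ELN against TNF+CBD was the member that passed in a comparison of compounds, but it did not pass with no intensity trend (adjusted p = 0.0535), after cyclic loess (0.0504), with the replicate block (0.0602) or without any of the 4 arrays in turn (0.0544 to 0.575). The arrays measured mRNA, and levels of the lipids were not analysed here.

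Inflammatory and lipid genes outside that system were followed in the same way. IL36G and MMP9, genes of inflamed epidermis, were at -0.03 ± 0.17 and 0.08 ± 0.18 in TNF against CTL, and ANGPTL4, a PPAR target, at 0.25 ± 0.23. Mean signals of IL36G and MMP9 were 5.19 and 5.85 log2, where the 95th percentile of the negative controls reached 4.99. IL36G thus lay close to background, where little change can show. KRT10 and KRT14 had means below the filter and were not tested. In TNF+BAK+ELN against TNF, TNFAIP3 was at -0.30 ± 0.16, NFKBIA at -0.34 ± 0.13, ICAM1 at -0.30 ± 0.13, CXCL8 at -0.13 ± 0.27, CCL20 at -0.73 ± 0.30 and IL1B at -0.19 ± 0.21, and none passed. With CBD they were at 0.19 ± 0.16, 0.00 ± 0.13, 0.24 ± 0.13, 0.61 ± 0.27, 0.82 ± 0.30 and 0.58 ± 0.21.

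The genes that TNF changed were then asked to show whether a compound moved them back. By limma 0 of the 1217 passed in the other direction with any of the 4 treatments, counted at an adjusted p under 0.05. As a group they lay closer to CTL with the combination: 585 of the 645 raised genes (90.7%) were lower than with TNF, with a median of -0.24, and 503 of the 572 lowered genes (87.9%) were higher, with a median of 0.20. Simulations with no effect and the shared TNF arrays gave mean medians of -0.013 and 0.021, and a mean covariance with the TNF effect of -0.0117 where the observed one was -0.0461. They leave out movement that genes share on an array, so they give the value that shared arrays add and no test. Part of the difference may come from the TNF arrays, whose means of the raised genes were 8.71 and 8.52. With BAK the medians were -0.060 and 0.068, with ELN -0.028 and 0.050, and with CBD 0.088 and -0.024.

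These medians moved with single TNF arrays, but that of the combination stayed below 0. With 1 TNF array used to choose the genes and the other as control, the raised genes had medians of -0.18 and -0.32 with the combination, 0.050 and -0.15 with BAK, 0.090 and -0.094 with ELN, and 0.25 and -0.0039 with CBD. For the combination the median was -0.15 without TNF+BAK+ELN replicate 1 and -0.37 without TNF replicate 2, and that of the lowered genes was 0.080 and 0.32. The direction turned for BAK without TNF replicate 1 (0.011), for ELN without TNF replicate 1 (0.057) or TNF+ELN replicate 1 (0.0037), and for CBD without TNF replicate 2 (-0.010). In comparisons that hold no TNF-only array the raised genes had a median of -0.18 in the combination against TNF+BAK (86.7% below 0), -0.21 against TNF+ELN and -0.32 against TNF+CBD. The mean of the raised genes was 8.34 ± 0.077 log2 (SD, n = 2) with the combination and 8.62 ± 0.111 (n = 6) over the 3 single compounds, a difference of -0.28. Those compounds had means of 8.55 with BAK, 8.57 with ELN and 8.74 with CBD, which is not part of the combination. The exact two-sided permutation p was 0.0714, which is 2 times the one-sided p and the smallest that this can give over 28 splits. The lowered genes had 7.57 ± 0.159 and 7.38 ± 0.041, with the same p (0.0714 adjusted over both). This test treats arrays of 3 treatments as alike, so it does not set the combination against its own parts.

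**Figure D4:**
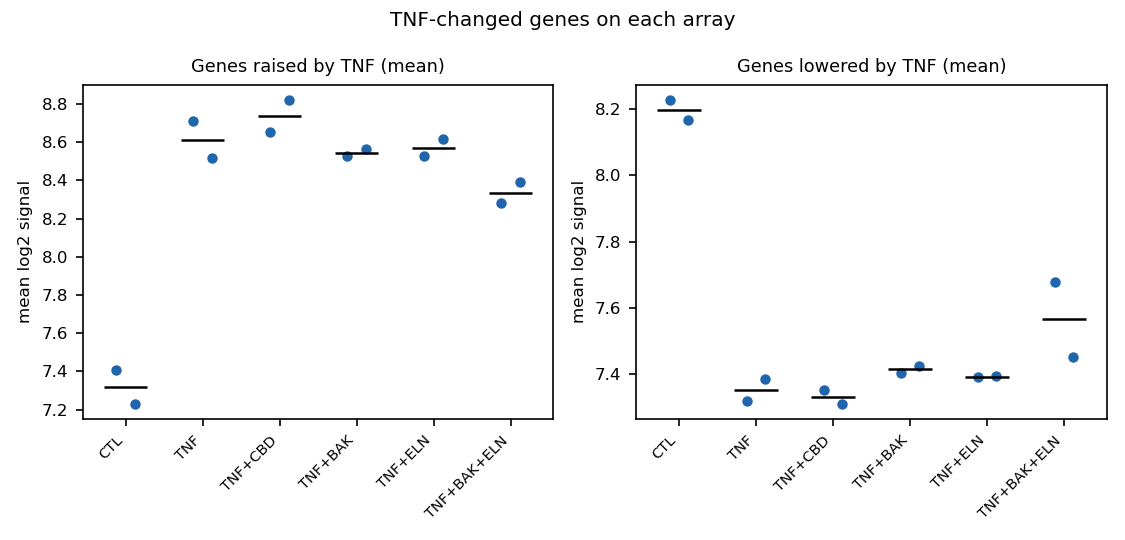
Mean log2 signal of the 645 genes raised and the 572 genes lowered by TNF on each array (points; bars are group means) in the 6 groups of 2 arrays. With TNF+BAK+ELN the raised genes have a mean of 8.34 and the lowered genes 7.57, between CTL (7.32 and 8.20) and TNF (8.61 and 7.35).

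Effects of the compounds were set side by side in pairs. The covariance of the log2 differences from TNF across genes was 0.0147 for BAK and the combination and 0.00621 to 0.00872 for the other 5 pairs, beside a simulated mean of 0.0116 that the shared TNF arrays give with no effect. The simulations leave out movement that genes share on an array, and 5 of the 6 pairs lay below them, so no shared effect is read from these values.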

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

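The test of transcript clusters without a gene name was chosen only after the data were seen. Of 2385 such clusters above the filter, 121 changed in TNF against CTL by limma, 75 of them higher and 46 lower with TNF. They came to attention as a signal in data that no comparison of named genes uses. In the comparisons of each compound with TNF and in the interaction 0 of them changed by limma (37 to 159 at an unadjusted p under 0.05), while 6 changed in TNF+BAK+ELN against TNF+CBD and 1 in TNF+BAK against TNF+CBD. What these clusters encode was not analysed here.

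For 7 gene lists the effect of the combination differed from the sum of the effects of BAK and ELN in camera's test of the interaction itself. The medians were -0.23 for NF-kB genes, -0.17 for chemokines, -0.59 for interferon genes, 0.15 for cell cycle genes, -0.19 for fatty acid synthesis and LXR targets, -0.19 for EGFR ligands and immediate early genes, and -0.32 for endothelial markers. Values below 0 mean that the list lay lower with the combination than the sum of the single effects. Not one of the 7 calls held where the correlation between genes came from the arrays: adjusted p = 0.517, 0.568, 0.547, 0.310, 0.547, 0.505 and 0.503 with an estimated correlation, in the same order. limma called 0 genes in the interaction, with 595 at an unadjusted p under 0.05. The interaction includes TNF+ELN replicate 1, the array that stood apart, and without it the endothelial call was lost (median -0.13, adjusted p = 0.220). The interferon median was -0.16 without TNF replicate 2 and -1.12 without TNF replicate 1. That of NF-kB genes was -0.115 without TNF+BAK+ELN replicate 1. The chemokine median was -0.091 without TNF replicate 2 and -0.27 without TNF+BAK+ELN replicate 2, and the fatty acid median -0.34 without TNF+BAK replicate 1. No explanation of these list differences was tested. The doses are not given in the labels, so the sum need not be the value without an interaction.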

How the results depend on the processing

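The settings that leave out TNF+ELN replicate 1 of every fit, or the TNF+ELN group, were chosen only after seeing the data. Leaving out that array raised the genes called by limma in TNF against CTL to 1932, in TNF+CBD against TNF to 44, in TNF+BAK+ELN against TNF+CBD to 302 and in TNF+BAK against TNF+CBD to 61, with 5 TNF-changed genes moved back by CBD. Leaving out the group gave 1932, 44, 303 and 61. Both remove the widest group, whose spread was 1.68 times the pooled spread, from the shared estimate. A fit of the compared groups alone called 5 genes in TNF+CBD against TNF, 17 in TNF+BAK against TNF, 24 in TNF+BAK+ELN against TNF, 29 in TNF+BAK+ELN against TNF+BAK, 244 in TNF+BAK+ELN against TNF+CBD and 108 in TNF+BAK against TNF+CBD. Array weights gave 59 in TNF+CBD against TNF, 21 in TNF+BAK+ELN against TNF, 256 in TNF+BAK+ELN against TNF+CBD and 106 in TNF+BAK against TNF+CBD. For these 2 settings the cause was not tested. Of the other counts under changed settings 121 stayed within 1.5 times the reported ones, and 1, with the replicate block, did not and is given below.

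With single arrays left out, the count ranged from 559 to 892 in TNF against CTL, 0 to 28 in TNF+CBD against TNF, 0 to 1984 in TNF+ELN against TNF, 0 to 1256 in the interaction, 0 to 2291 in TNF+BAK+ELN against TNF+ELN, 1 to 68 in TNF+BAK+ELN against TNF+CBD and 0 to 12 in TNF+BAK against TNF+CBD. Genes moved back ranged from 0 to 1 with CBD and 0 to 267 with ELN. The highest values for ELN came without TNF+ELN replicate 2, where replicate 1 stands alone and is assumed to vary like the other groups. A few values reversed: GADD45A in TNF+ELN against TNF was 0.021 without TNF+ELN replicate 1 (lowest value -1.14, without TNF+ELN replicate 2), CRYAB in TNF+BAK+ELN against TNF+CBD was -0.042 without TNF+BAK+ELN replicate 1 (highest value 0.54, without TNF+BAK+ELN replicate 2), and the interferon list in TNF+CBD against TNF was -0.12 without TNF replicate 2 (highest median 0.65, without TNF replicate 1). The cause was not tested.

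Of the 83 called lists 48 had a median that moved by over 1.5 times without at least 1 array, 14 of them with the call kept, and 5 medians changed sign. Of the 83 list calls 0 were kept with an estimated correlation, 25 with fry, 72 of the 82 that could be tested with the filter at the median, 76 after cyclic loess, 78 with arrays centred on their medians and 78 with no filter. With the replicate number as a block 78 were kept, and TNF+BAK+ELN against TNF+CBD had 19 genes, 18 of them among the 36. The labels do not state a pairing: between groups the replicate differences correlated across genes at -0.179 to 0.136, above 0.1 in 1 of 15 pairs of groups. Genes near the negative controls, whose 95th percentile reached 4.99 log2, can show little change on these arrays.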

Other observations

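The tests of a fibroblast-like culture and of a quality difference shared with CTL replicate 2, and the counts of epithelial genes above the controls, were chosen only after the result was seen. In TNF against CTL 19 lists were not called by camera, and some of their members changed; these were chosen after their values were seen. In the integrated stress and unfolded protein response (median 0.16, adjusted p = 0.0520) ATF3 rose by 1.46 log2, the splicing target XBP1 by 1.12 and the chaperone HSPA5 by 0.57, while PSAT1 and PHGDH, enzymes of serine synthesis, changed by -0.85 and -0.71. Among EGFR ligands and immediate early genes (-0.08, 0.175) EREG rose by 1.54, JUNB by 1.40 and JUN by 0.82, and DUSP4 changed by -0.64. Among fibroblast markers (-0.35, 0.254) LUM rose by 3.04 and DCN by 0.53, while THY1, COL6A3 and PDGFRB changed by -0.77, -0.71 and -0.66. NRF2 targets (0.03, 0.407) included CBR3 at 0.97 and EPHX1 at -0.85, and hypoxia and glycolysis genes (-0.05, 0.581) CA12 at 1.21 and PFKFB3 at -0.68. Heat shock genes (-0.05, 0.988) included DNAJA1 at 1.42 and CRYAB at -1.15.

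Among lipid and retinoid lists, cholesterol synthesis (0.12, adjusted p = 0.372) included ACAT2 at -1.08, fatty acid synthesis and LXR targets (-0.18, 0.687) ELOVL7 at 2.00 and SREBF1 at -0.78, PPAR targets (-0.17, 0.211) PLIN2 at 0.73 and ACAA2 at -0.46, and the retinoid response (-0.04, 0.832) PLAAT4 at 1.49 and CRABP2 at -0.55. p53 targets (-0.06, 0.674) included PLK3 at 0.47 and ZMAT3 at -0.70, and the endocannabinoid list had -0.11 (0.738). Antimicrobial and S100 genes (0.07, 0.506) included RNASE7 at 0.73, basal keratinocyte genes (0.02, 0.415) ASS1 at 0.74 and ITGA3 at -0.61, and endothelial markers (-0.06, 0.506) KDR at 1.68. Keratinocyte differentiation (-0.05, 0.825), melanocyte (-0.15, 0.693), immune (0.01, 0.830) and Merkel cell markers (-0.07, 0.970) had 0 members past limma's threshold. The median lay below 0 and the mean above 0 for heat shock, retinoid, EGFR, hypoxia and endothelial lists; no called list differed in this way.

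KRT14, ITGB4, ITGA6, DSG3, GRHL2 and ESRP1, genes of epidermal epithelium, lay near the negative controls while most fibroblast markers gave high signals, under a keratinocyte label. Of 46 abundant epithelial genes 26 lay above the controls on all 12 arrays, where 71.9% of all named genes did, and 8 on none. Keratin probe sets that do not work leave other genes alone, so they cannot account for the low genes that are not keratins: 8 of these 41 lay above the controls on no array. For KRT14 this explanation stays open. Keratinocytes with some fibroblasts among them would keep the abundant epithelial genes high. The median of these genes lay at percentile 37.1 of named genes (36.2 without keratins), and at 35.2 to 43.9 on single arrays. By the bounds set beforehand, a median below percentile 50 counted against this explanation. These values therefore argue against it, for these genes as a set. Ranks between genes also depend on how strongly each probe set responds, so an admixture is not excluded: MFAP5, a fibroblast marker, had 4.76 and DCN 12.25. A fibroblast-like culture was the other explanation. For it, the median of the fibroblast markers at percentile 96.6 on the lowest array restates the observation. The design names no other cell type, so the identity of the cells was not tested directly. The highest basal keratinocyte genes, ITGB1, CD44 and CAV1, are also expressed by fibroblasts.

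TNF+ELN replicate 1 stood apart from the other TNF-treated arrays. A response to ELN would appear on both TNF+ELN arrays, but their deviations from the 8 other TNF-treated arrays correlated at 0.0772 across genes. Noise across the whole array cannot be told apart from other causes, since its negative controls deviated 1.11 times as much as the median of the other 11 arrays, which ranged from 0.847 to 1.18. A quality difference shared with CTL replicate 2 could also contribute: the array's deviation correlated at 0.176 with the difference between the CTL arrays, against -0.162 to 0.108 for the 8 other arrays. Positive controls had a median of 9.36 on both arrays and 9.48 to 9.53 elsewhere. ERCC control rows had medians of 4.65 and 4.66, against 4.46 to 4.58 elsewhere. These control medians were compared after the values were seen. CTL has 2 arrays, so the test stays open. Such a difference would also enter TNF against CTL, which holds CTL replicate 2.

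Cholesterol synthesis genes lay lower with CBD, BAK and the combination than with TNF alone, in comparisons that share the TNF arrays. For CBD and BAK this stays open, since neither was compared with TNF+ELN. Their list means were 8.81 and 8.29 log2 on the TNF+CBD arrays and 8.79 and 8.95 on the TNF+BAK arrays, beside 8.94 and 9.38 on the TNF+ELN arrays. The CTL arrays, at 9.22 and 9.28, lay above those of CBD and BAK. They had no TNF, so they cannot show where arrays with TNF alone would lie without chance. For the combination, if the TNF arrays were high by chance, a comparison without them would show no difference, but TNF+BAK+ELN minus TNF+ELN had a median of -0.58, from -0.81 to -0.40 over pairs of arrays. A lower level of the pathway with the combination may underlie its part of the pattern, as a hypothesis found and tested on the same data. The list had adjusted p = 0.415 with an estimated correlation in that comparison, and the call was lost without TNF+ELN replicate 2 (median -0.56, adjusted p = 0.0595).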
